A study of Homo sapiens with 10 samples.

How the data were processed

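Total RNA of K562 cells was measured on 10 spotted arrays with 2 dyes. The titles of both BMSR samples spell the line K563, which was read as K562 from their source names. Per the labels, RNA was extracted with RNeasy columns, checked by NanoDrop and Bioanalyzer and labelled with a LabelStar kit. On 9 arrays the sample carried Cy5 and the mock reference Cy3, and on BMSR replicate 2 the dyes were the other way round. The replicate numbers come from the sample titles, and nothing in the labels says whether the 2 arrays of a group came from separate cultures, so the p-values may measure technical spread only.

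The deposited values are in the unit log2, computed as the log10 of a ratio divided by 0.301. Between 66.2% and 98.7% of the values per array are ratios of 2 whole numbers (relative tolerance 1.2e-07, product of the 2 numbers at most 300000), where 1.02% to 2.77% would be by chance. No scaling per array by the authors is therefore seen in them, and background correction and any filter are not given in the sources used here. Missing values numbered 198 to 721 spots per array. The larger recovered whole number served as a lower bound of spot signal, and spots where it was under 20 were counted as dim: 52.7% of the values on BMS replicate 1, 41.9% on imatinib replicate 1, 40.6% on combination replicate 1, 40.2% on BMSR replicate 2, and 5.36% to 12.2% on the other 6 arrays. The 3 copies of a spot correlated with r from 0.278 to 0.892, and their median SD per array lay between 0.34 and 0.87 log2 units. The highest correlations of copies were those on BMSR replicate 2, from 0.844 to 0.892.

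The order of the channels in the deposited ratio is not stated. The 9 arrays with the sample in Cy5 were read as sample over mock, which is likely but not certain. For the dye-swapped array a rule was fixed before the data were examined: it was kept as deposited if its correlation with BMSR replicate 1 over spots was above 0.3. That correlation was 0.301 over 1349 spots, just past the rule, and 0.136 after the mean of the 8 other arrays was subtracted. Its correlations with single arrays ran from 0.234 to 0.301. The array was kept as deposited, and calls, list medians, profile correlations and the values of named genes that use it were also computed with its sign turned.

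Of 2100 spots, 1827 carried 1 gene symbol, 0 carried several and 273 had no gene in the annotation used and stayed under their spot number. The symbols name 598 genes, 587 with 3 spots and 11 with 6. Spots of a gene were averaged, each array was centred on its median over the genes tested, and the 452 entries with a value on all 10 arrays were tested, 401 named genes and 51 unnamed spots. The medians removed ran from -0.385 (IMR replicate 1) to 0.252 (BMSR replicate 2), and their group means were -0.024 for BMS, -0.114 for imatinib, 0.072 for the combination, -0.172 for IMR and 0.107 for BMSR.

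A group-means model was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, 5 residual degrees of freedom, prior degrees of freedom 4.32, prior SD 1.05), 2-sided, with Benjamini-Hochberg adjustment over all entries and a threshold of 0.05. Each group was tested against 0, since the reference on every array is the control RNA itself; that test leaves out the spread of the control. Further comparisons were BMS minus imatinib, combination minus the mean of both single exposures, IMR minus BMSR, and the clones minus the short exposures. These 9 comparisons were fixed before the data were examined, and 3 means against mock (short exposures, clones, all 10 arrays) were added afterwards. Simulated data with the spread of the fit and independent arrays were used to test how often a change of a given size is called: for 2 arrays against mock a log2 change of 1 was called in 3.5% of the 400 genes given it (over 20 sets of 452 genes), 2 in 22%, 3 in 67.3% and 4 in 93.3%. The 4 sizes were given to different genes of the same sets, 400 each over all sets, beside 7440 unchanged. Many changed genes make the adjusted threshold easier to pass. These shares are therefore likely too high for a comparison in which few genes change.

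Of 32 gene lists fixed before the data were examined, 28 had a gene on the array and 10 had at least 5 genes measured on all arrays. These 10 were tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), with an estimated correlation and with fry, which tests a list against no change and not against other genes. They cover G1/S, G2/M, chaperones, STAT5 targets, signal transduction, p53 targets, pro-apoptotic and anti-apoptotic genes, NF-kB and adhesion. In 17 of the 90 list tests the median of the members had the opposite sign to the test, and in 6 the mean had, none of them with an adjusted p below 0.651.

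Genes are named by a rule fixed in the same way. It takes, per comparison, up to 12 called genes in each direction that changed the same way on both arrays of each group, and where fewer than 10 genes pass, also the 6 highest and 6 lowest values among genes whose 2 arrays have the same sign, or, for a difference, whose values on the 2 sides do not overlap, given as values. To these it adds 18 genes fixed by name and 2 to 4 members of each list. Profile correlations are given beside 200 simulations of unchanged groups that share 1 mock RNA. Simulations in which the short exposures also share part of their spread by replicate number were added after seeing the data.

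The replicate differences of the 3 short exposures correlated with each other across genes (r 0.325 to 0.401), while those with and between the clones ran from -0.0311 to 0.169. The replicate number was therefore tried as a block and not used as the default. Other alternatives were no centring, scale normalization, each spot on its own, a trended and robust prior, genes with values in the compared groups, only the arrays compared, and leaving out each array in turn. Chosen after seeing the data were leaving out dim spots, centring within 5 bins of spot signal, and turning the sign of BMSR replicate 2 for lists and for named genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.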

Results

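RNA levels were measured in K562 cells, a human chronic myeloid leukaemia line that carries the BCR-ABL fusion kinase, on 10 arrays with 2 dyes each. On each array a sample was hybridised together with RNA of mock-treated K562 cells, and each value is the log2 ratio of the 2 channels at a spot, read here as sample over mock, the likely direction, since the labels do not state the order of the channels. The 5 groups held 2 arrays each. BMS-354825 (dasatinib), an inhibitor of ABL and SRC family kinases, was given at 10 nM for 12 h, and imatinib, an inhibitor of ABL, KIT and PDGF receptor kinases, at 5 µM for 12 h. A further group received both inhibitors, with dose and time not given in the sources used here. The remaining groups were resistant clones: IMR, selected from 0.1 µM imatinib and growing in 10 µM, and BMSR, selected from 0.5 nM BMS-354825 and growing in 10 nM. The arrays carried 2100 spots, 700 sequences in 3 copies, and named 598 genes. Between 1379 and 1902 spots per array had a value, and 401 named genes and 51 spots with no gene name had one on all 10 arrays.

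Spot signal differed between arrays. The larger of the 2 whole numbers that give back each ratio had a median of 19 on BMS replicate 1, 24 on imatinib replicate 1, 28 on combination replicate 1 and 35 on BMSR replicate 2. It lay between 110 and 343 on the other 6 arrays. Common factors cancel in a ratio, so these numbers are lower bounds of the signal. The 2 arrays of a group correlated across genes with r = 0.0573 for BMS, 0.129 for imatinib, 0.183 for the combination, 0.291 for IMR and 0.249 for BMSR. Arrays of different short exposures with the same replicate number correlated more closely, with r from 0.36 to 0.548 over 6 pairs, against 0.078 to 0.202 over the 6 pairs with different numbers. The number of arrays limits the precision of every value given here. Genes at least 2-fold higher on both arrays numbered 18 for BMS (14.7 by chance), 19 for imatinib (19.9) and 10 for the combination (9.99). At least 2-fold lower were 38 (27.4), 33 (22.3) and 26 (18.1). IMR had 57 higher (25.2) and 44 lower (25.3), and BMSR as deposited had 27 (16.9) and 56 (23.2). The high values named below for single short exposures are therefore not shown to be responses.

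**Figure D1:**
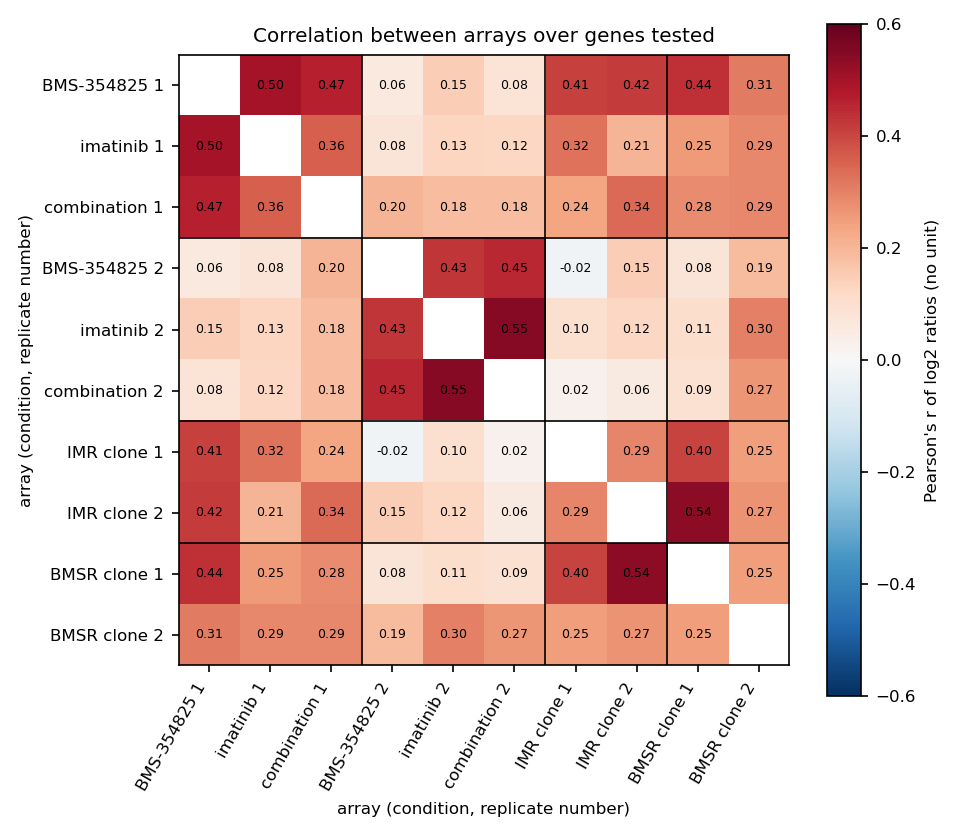
Pearson's r (no unit) between the log2 ratios of each pair of arrays over 452 genes and spots; both axes list the 10 arrays by condition and replicate number, and black lines part the short-exposure replicate 1 arrays, the short-exposure replicate 2 arrays and the 2 resistant clones. The short-exposure arrays sit closer to arrays of the same replicate number (0.36 to 0.548) than to the other array of their own group (0.0573 to 0.183).

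The first question was what each inhibitor did to the cells within hours. After BMS-354825, genes of DNA replication and the G1/S transition lay low as a group, with 12 of 16 measured members below mock and a median log2 ratio of -1.07. Among them were UNG, a uracil-DNA glycosylase of replicating cells (mean log2 ratio -3.48 ± 2.34, SD, n = 2 arrays, as for every ± below), PCNA, the sliding clamp of DNA polymerases (-2.64 ± 1.42), the clamp loader subunit RFC4 (-2.38 ± 0.46) and the S phase cyclin CCNA2 (-1.92 ± 0.07). The D-type cyclin CCND2 had -3.21 ± 0.67, and the transferrin receptor TFRC, which brings iron into dividing and erythroid cells, had -2.61 ± 0.28. Also among the lowest values were the chaperone HSP90AA1 (-3.34 ± 1.93), the nucleolar protein NCL (-2.70 ± 2.34) and the HSP70 cofactor BAG1 (-2.62 ± 2.13). High values were those of the chemokines CXCL11 (2.16 ± 1.15) and CCL11 (1.94 ± 0.66), of CTNND2 (2.13 ± 0.52), of the transcription factor ATF7 (2.12 ± 1.49), of CARD14 (1.95 ± 1.26) and of DNASE2B (1.89 ± 1.16).

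No gene passed the test after BMS-354825 at an adjusted p under 0.05 (limma). At an unadjusted p under 0.05 there were 38 genes, 8 higher and 30 lower than mock, where 22.6 would come by chance, and the lowest adjusted p was 0.348. The G1/S list was lower than the other genes (camera, adjusted p = 0.0374 with a preset correlation of 0.01, adjusted p = 0.641 with an estimated correlation). Tested against no change in place of the other genes, it had an adjusted p of 0.273 (fry). Of its 16 members, 0 were called over all genes tested and 4, all lower, when adjusted over the list alone. The call needed replicate 1, an array of low signal, without which the adjusted p was 0.482. It also ended with a block for replicate number (0.0607), without either imatinib array (0.0528 each), without dim spots (0.274), with centring by signal (0.0556) and with the sign of BMSR replicate 2 turned (0.0633), the range over all alternatives being 0.0268 to 0.641. The other 9 lists had adjusted p from 0.178 to 0.823.

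After imatinib, the chaperone genes lay low, with 7 of 8 members below mock and a median log2 ratio of -1.44. The cytosolic chaperone HSP90AA1 had -3.80 ± 3.58, its values on the 2 arrays being -6.33 and -1.27. Lower spread was seen for the HSP70 partner DNAJA1 (-2.37 ± 0.16), and the stress-inducible HSP70 genes HSPA1B and HSPA1A had -1.86 ± 1.61 and -1.62 ± 0.93. Other low values were those of the mitotic kinesin CENPE (-2.74 ± 1.78), the growth factor VEGFB (-2.59 ± 2.17), the oestrogen receptor ESR2 (-2.58 ± 2.07), the keratin KRT5 (-2.45 ± 1.63) and SOCS2, a feedback inhibitor of JAK-STAT signalling (-2.43 ± 2.07). High values were those of HGFAC, the activator of hepatocyte growth factor (3.06 ± 2.84), the chemokine CXCL13 (2.96 ± 0.49), the translation repressor PDCD4 (2.84 ± 2.08), the RANK receptor TNFRSF11A (2.51 ± 0.66), the tight junction protein CLDN2 (2.29 ± 0.65) and the chemokine receptor CXCR3 (2.16 ± 0.63).

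With imatinib no gene passed the test (limma), 54 genes had an unadjusted p under 0.05, 23 higher and 31 lower, and the lowest adjusted p was 0.416. The chaperone list was lower than the other genes (camera, adjusted p = 0.00614, adjusted p = 0.769 with an estimated correlation), with 0 of 8 members called over all genes and 2, both lower, adjusted over the list alone. Against no change its adjusted p was 0.122 (fry). Without imatinib replicate 1, an array of low signal, its adjusted p was 0.0545, and over all alternatives it ran from 0.00711 to 0.769. The other 9 lists had adjusted p from 0.83 to 0.839. The G1/S list had 8 of 16 members below mock and a median of -0.40 (adjusted p = 0.83).

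**Figure D2:**
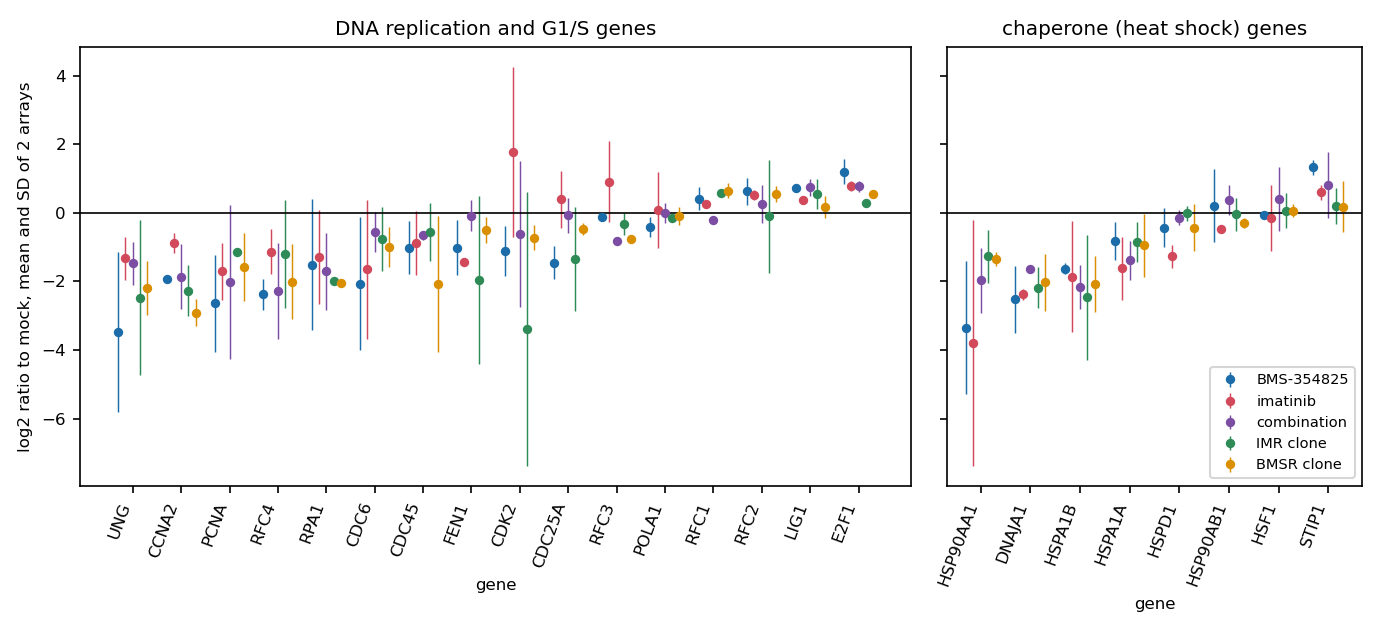
Mean log2 ratio to mock (y axis; points, with bars of 1 SD over 2 arrays) of the 16 measured DNA replication and G1/S genes and the 8 measured chaperone genes (x axes), ordered by their mean over the 10 arrays and coloured by condition. With BMSR replicate 2 as deposited, UNG, CCNA2, PCNA and RFC4 lie below 0 in all 5 conditions, as do HSP90AA1, DNAJA1 and HSPA1B, while E2F1 and STIP1 lie above 0; with its sign turned, 12 of the 16 and 5 of the 8 genes lie above 0 in BMSR.

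Cells given both inhibitors had low values of the cyclin CCND2 (-2.82 ± 0.47), the connexin GJB1 (-3.19 ± 2.06), the low-affinity IgE receptor FCER2 (-3.03 ± 0.37), the growth factor EGF (-2.72 ± 2.59), BAG1 (-2.47 ± 0.92) and the RHOA exchange factor NET1 (-2.37 ± 1.78). High values were those of the chemokine CCL5 (2.61 ± 2.70), the interleukin 2 receptor chain IL2RA (2.41 ± 1.49), the matrix protease MMP3 (2.39 ± 0.44), the erythrocyte membrane protein ANK1 (2.21 ± 0.20), the cytokine TNFSF14 (2.10 ± 1.60) and the cyclin CCNA1 (2.03 ± 1.78). The G1/S list had 13 of 16 members below mock and a median of -0.58, without passing the test (adjusted p = 0.174). No gene passed the test (limma), 28 had an unadjusted p under 0.05, 12 higher and 16 lower, and the lowest adjusted p was 0.578. The 10 lists had adjusted p from 0.174 to 0.593.

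Whether the combination differed from the inhibitors given alone was tested against the mean of the 2 single exposures. Among genes whose 2 combination values lay both above or both below the 4 of the single exposures, the largest positive differences were those of NCL (3.36, 95% interval 0.91 to 5.80), MMP3 (2.64, 0.95 to 4.33) and the transcription factor TFAP2B (2.31, 0.22 to 4.40). The largest negative ones were those of EGF (-3.38, -6.16 to -0.61), FCER2 (-3.13, -5.85 to -0.42) and the lipoprotein receptor LRP1 (-2.71, -4.93 to -0.49). None passed the test (limma, lowest adjusted p 0.999), 10 genes had an unadjusted p under 0.05, fewer than the 22.6 due to chance, and the lists had adjusted p from 0.602 to 0.932. The replicate differences of the 3 groups correlated (r 0.325 to 0.401), which the test leaves out, so it may be too strict.

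The 2 inhibitors were compared directly, at doses that differ, 10 nM against 5 µM. The interferon-induced chemokine CXCL11 was 4.17 higher on the log2 scale after BMS-354825 than after imatinib (95% interval 1.61 to 6.74), its group means being 2.16 and -2.01. The B-cell chemokine CXCL13 had a difference of -3.09 (-5.65 to -0.53), and the ubiquitin ligase BIRC6 and the receptor TLR1 had -3.23 and -3.08. No difference passed the test (limma, lowest adjusted p 0.991) and 7 genes had an unadjusted p under 0.05, 2 of them higher after BMS-354825. The 95% intervals had a median half-width of 2.44, 24 of 452 lay within 2 log2 units of 0 and 0 lay within 1, so the comparison does not show that the inhibitors act alike. The test took the arrays as independent, while the replicate differences of the 2 groups correlated (r = 0.401). It may therefore be too strict and its intervals too wide. With a block for replicate number 11 genes had an unadjusted p under 0.05 and 0 passed (limma). In simulated data of independent arrays a difference of 3 log2 units was called in 18.8% of the genes given it. Many genes were changed in those data, so this share is likely too high for a comparison where few genes change. G1/S genes lay lower after BMS-354825 in 11 of 16 members and chaperone genes higher in 7 of 8, both at an adjusted p of 0.176, and the 10 lists ranged from 0.176 to 0.766.

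Across genes, the mean profiles of the 3 short exposures correlated with r = 0.526 (BMS-354825 and imatinib), 0.541 (BMS-354825 and combination) and 0.491 (imatinib and combination), with Spearman's rho of 0.513, 0.555 and 0.519. Correlations between a short exposure and a resistant clone ran from 0.283 (combination and IMR) to 0.452 (BMS-354825 and BMSR), and the 2 clones correlated with r = 0.547 (rho 0.59). The median over the 10 pairs of groups was 0.431. The resemblance of short exposures to clones lay mainly with their replicate 1 arrays, which had low signal. Those had r from 0.206 to 0.436 with both IMR arrays and BMSR replicate 1. The replicate 2 arrays had -0.0212 to 0.149. With BMSR replicate 2 as deposited the ranges were 0.287 to 0.311 and 0.192 to 0.304. Genes are not independent replicates, and the groups may share 1 preparation of mock RNA, which the sources used here do not state: simulated groups with no change that shared 1 mock RNA, as variable as the replicates were, had a mean r of 0.667 (SD 0.0233), and without a shared mock -0.00136. Where the unchanged short exposures also shared part of their spread by replicate number, as measured, their simulated r was 0.36 (SD 0.0364) without a shared mock and 0.786 (SD 0.0191) with one. The value without a shared mock follows directly from the correlation of replicate differences put into the simulation (0.361). With the sign of BMSR replicate 2 turned, the correlations of BMSR with BMS-354825, imatinib and the combination were -0.0323, -0.147 and -0.12, and that of the 2 clones was 0.142.

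The second question was how the resistant clones differed from the parental cells. Per the labels IMR was growing in 10 µM imatinib and BMSR in 10 nM BMS-354825, whereas the reference cells were mock-treated. Resistance and ongoing exposure can therefore not be told apart. With a single clone per inhibitor, neither can resistance and a trait of that clone alone. In the imatinib-resistant IMR clone, the neural cell adhesion molecule NCAM1 had a mean log2 ratio of 4.11 ± 0.93, the HSP70-related HSPA4L 4.04 ± 2.37, the transcription elongation kinase CDK9 3.74 ± 3.07, the caspase inhibitor XIAP 3.54 ± 1.02, the apolipoprotein APOB 3.35 ± 0.15 and CGRRF1 3.34 ± 1.45. Low values were those of the adaptor SHC3 (-3.87 ± 2.25), the transcription elongation factor homologue TCEAL1 (-3.70 ± 0.86), the leukocyte integrin ITGAL (-3.48 ± 2.25), the cell cycle kinase CDK2 (-3.38 ± 3.99), the topoisomerase TOP2B (-3.37 ± 2.36) and the CD30 ligand TNFSF8 (-3.35 ± 2.55). The drug efflux pump ABCB1, the multidrug resistance gene, had 1.16 ± 0.65, against -0.45 ± 2.19 in BMSR and -0.37 ± 0.60 after imatinib, but it had 0.72 ± 0.27 after BMS-354825, and BMSR had 1.55 ± 0.64 with the sign of its replicate 2 turned. The lipid transporter ABCA3 had 2.98 ± 2.66. Of the G1/S genes, 13 of 16 lay below mock, with a median of -0.95 (adjusted p = 0.0862). No gene passed the test (limma): 76 had an unadjusted p under 0.05, 25 higher and 51 lower, and the lowest adjusted p, that of APOB and TCEAL1, was 0.0781. With a block for replicate number 6 entries passed: APOB higher, and TCEAL1, SHC3, ITGAL, TNFSF8 and an unnamed spot lower. The 10 lists had adjusted p from 0.0862 to 0.916.

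In the BMS-354825-resistant BMSR clone 1 gene passed the test: RELB, a subunit of the non-canonical NF-kB transcription factor, rose with a mean log2 ratio of 4.43 ± 1.58 (95% interval 2.87 to 5.98, limma adjusted p = 0.048), at 3.31 and 5.54 on the 2 arrays. Its usual partner NFKB2 had 3.54 ± 2.69. Other high values were those of IL2RA (4.17 ± 5.78), the chemokine CCL17 (3.84 ± 2.81), the pro-apoptotic BID (3.40 ± 0.27) and the OX40 ligand TNFSF4 (3.33 ± 4.29). Low values were those of the anaphase-promoting complex subunit ANAPC10 (-7.04 ± 0.95), the lipoxygenase ALOX5 (-4.10 ± 0.16), TOP2B (-3.46 ± 0.23), the adaptor MYD88 (-3.23 ± 2.45), the stress gene GADD45A (-3.02 ± 1.05) and the DNA methyltransferase DNMT3B (-3.01 ± 2.33). On replicate 1 the ANAPC10 value was the lowest of the array (-7.75 before centring). An average equals the lowest spot only if it rests on 1 spot or on copies with the same value. With a block for replicate number 4 genes passed, RELB, ALOX5, ANAPC10 and BID, each at an adjusted p of 0.044 (limma). With RELB included, 60 genes or spots had an unadjusted p under 0.05, 20 higher and 40 lower. The NF-kB list had 9 of 14 members above mock and a median of 0.47 (adjusted p = 0.322), with 1 called over all genes and 2 adjusted over the list alone. The 10 lists ranged from 0.0916 to 0.986.

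The call of RELB needed replicate 2, without which its value was 3.31 (adjusted p = 0.252; 5.54 and 0.0182 without replicate 1). It also ended when any 1 of the 6 short-exposure arrays was left out, with dim spots left out (4.73, adjusted p = 0.132) and with centring by signal (4.39, adjusted p = 0.0653), and its adjusted p over the alternatives ran from 0.0182 to 1. The number of calls was 9 without replicate 1 and 3 without either IMR array. Replicate 2 had its dyes the other way round, and with its sign turned RELB had -1.12 and 2 other entries passed, IL12B at -4.01 and an unnamed spot at 5.26. The low values were then -0.67 for ANAPC10, 0.12 for ALOX5, 0.16 for TOP2B, -1.73 for MYD88, 0.74 for GADD45A and 1.65 for DNMT3B. Of the high values, BID then had 0.19, NFKB2 -1.90, IL2RA -4.09, CCL17 -1.98 and TNFSF4 -3.03. The NF-kB list had 7 of 14 members above mock. Several immune genes, picked after their values were seen, stood apart on replicate 2: IL2RA had 8.26 there, 0.08 on replicate 1 and at most 3.79 on the other 8 arrays, and the chemokine receptor CCR8 had 6.50, -0.94 and at most 1.89. The lymphoid marker IL7R had 3.54 on replicate 2 and 0.23 on replicate 1, but the B-cell marker CD79A had a BMSR mean of -0.06 ± 0.09.

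**Figure D3:**
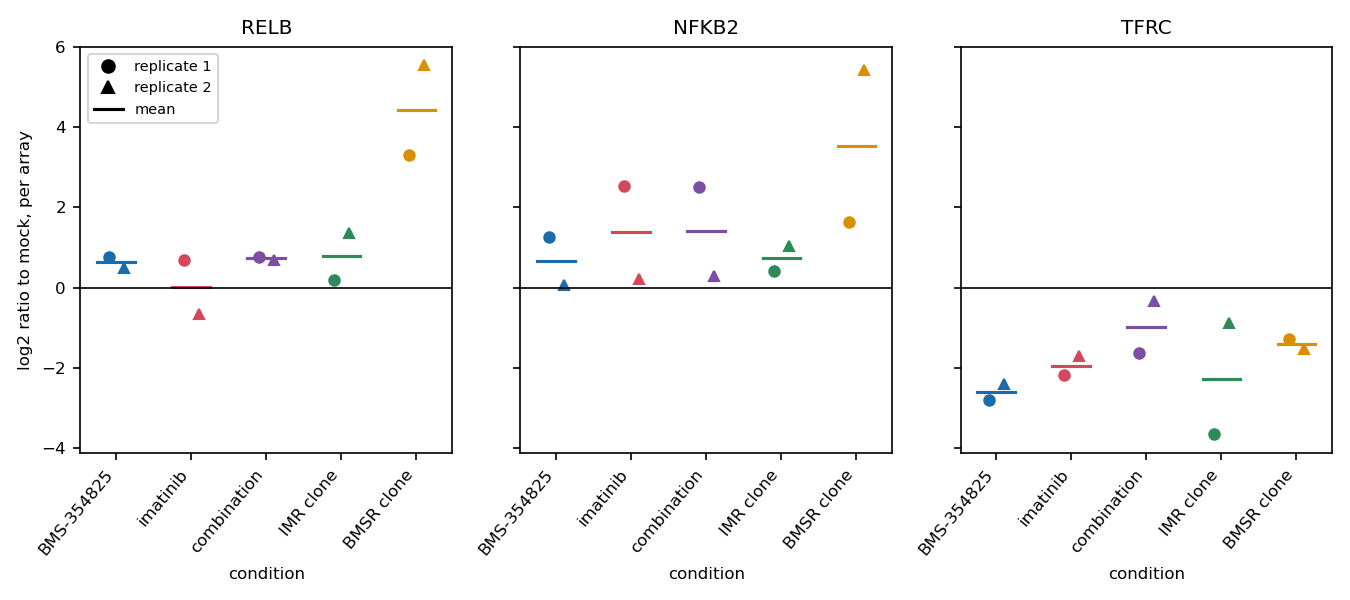
Log2 ratio to mock (y axis) of RELB, NFKB2 and TFRC on each array, by condition (x axis); circles are replicate 1, triangles replicate 2, and the horizontal bars the mean of the 2 arrays. RELB lies at 3.31 and 5.54 in the BMSR clone, and TFRC lies below 0 on all 10 arrays with BMSR replicate 2 as deposited.

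The 2 clones were set against each other. RELB was -3.64 in IMR minus BMSR (95% interval -5.84 to -1.44), the cyclin CCNG2 -2.80 (-4.65 to -0.95), the integrin ITGAL -3.49 (-6.15 to -0.82) and the chemokine CCL22 -3.48 (-6.75 to -0.21). ANAPC10 had 6.70 (1.62 to 11.8), the DNA repair helicase ERCC2 4.08 (1.12 to 7.04) and the p53 relative TP73 2.48 (0.13 to 4.83). No difference passed the test (limma, lowest adjusted p 0.997), 12 genes had an unadjusted p under 0.05, 6 in each direction, and the lists had adjusted p from 0.435 to 0.992. With the sign of BMSR replicate 2 turned there were also 0 calls (25 genes at an unadjusted p under 0.05, 15 higher and 10 lower), and the differences were 1.90 for RELB, 0.79 for CCNG2, 0.21 for CCL22, 0.32 for ANAPC10, 1.32 for ERCC2 and -2.71 for ITGAL. RELB passing in BMSR and not in IMR is therefore no shown difference between the clones.

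Set against the 3 short exposures, the 2 clones had higher mean values of HSPA4L (difference 4.53, 95% interval 2.27 to 6.79), NCAM1 (3.65, 1.87 to 5.43), the kinase MAP4K4 (2.80, 1.21 to 4.39) and the integrin ITGAX (2.10, 0.79 to 3.40). The developmental ligand WNT3 had a difference of -2.13 (-3.37 to -0.88), the kinase MAP3K10 -1.53 (-3.00 to -0.05) and CCL11 -1.34 (-2.46 to -0.22). CCND2 differed by 3.33 (1.22 to 5.44), its short-exposure means being -3.21, -0.88 and -2.82 and its clone means 0.29 and 1.76, but with the sign of BMSR replicate 2 turned the BMSR mean was -1.92 and the difference 1.49 (-0.58 to 3.55). No difference passed the test (limma, lowest adjusted p 0.202): 35 genes had an unadjusted p under 0.05, 22 higher and 13 lower in the clones. The lists had adjusted p from 0.549 to 0.978. Turning the sign of BMSR replicate 2 also gave no call, with 31 genes at an unadjusted p under 0.05, and differences of 2.22 for NCAM1, 3.26 for HSPA4L and -1.15 for WNT3. In simulated data a log2 change of 2 was called in 39.8% of the genes given it in this comparison, against 22% for 1 group of 2 arrays and mock. Many genes were changed in those data, so both shares are likely too high where few genes change.

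Some genes lay on the same side of mock in several groups, and comparisons that average groups were added after these values were seen. Over all 10 arrays 65 entries passed the test (limma), 13 higher and 52 lower, and 59 of them were named genes. Among the lowest were TOP2B (mean log2 ratio -2.64, 95% interval -3.43 to -1.85), HSP90AA1 (-2.35, -3.46 to -1.23), ALOX5 (-2.27), UNG (-2.19), GADD45A (-2.19), DNAJA1 (-2.14, on 10 of 10 arrays below mock), TCEAL1 (-2.12) and HSPA1B (-2.04). Cell cycle genes among those that fell were CENPE (-2.01), CCNA2 (-1.97), PCNA (-1.81) and RFC4 (-1.80), together with TFRC (-1.84, below mock on 10 of 10 arrays). Higher were NFKB2 (1.54), the growth hormone receptor GHR (1.37), the HSP90 cochaperone CDC37 (1.16), the thyroid hormone receptor THRA (1.15) and CASP2 (0.82). The G1/S list had 5 of 16 members called lower over all genes, and 9, 8 of them lower, adjusted over the list alone (camera, adjusted p = 0.0487, 0.811 with an estimated correlation). The chaperone list had 4 of 8 called lower (adjusted p = 0.0584, 0.811 with an estimated correlation). Against no change (fry) the 2 lists had adjusted p of 0.0315 and 0.0219. The anti-apoptotic list, with 4 members above mock and 5 below, had 0.0219 against no change (fry). Against the other genes it did not pass (camera, adjusted p = 0.785, 0.811 with an estimated correlation), and 1 of 9 members was called lower.

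The tests of averaged groups take the arrays as independent, although the replicate differences of the short exposures correlated (r 0.325 to 0.401). Their standard errors may therefore be too small, their intervals too narrow and their calls too many. A block for replicate number takes the shared part out of the spread and does not mend this. All 10 arrays have RNA of mock-treated cells as reference, whose own spread the test leaves out, and the sources used here do not state whether it was 1 preparation. With the sign of BMSR replicate 2 turned 0 genes passed (93 at an unadjusted p under 0.05, lowest adjusted p 0.172), and 17 passed without combination replicate 1, 24 without imatinib replicate 1, 27 without BMS replicate 1, 37 without IMR replicate 1 and 38 without BMSR replicate 2. The G1/S list lost its call with the sign turned (0.103), with the block (0.0718), without dim spots (0.84), with centring by signal (0.0843) and without BMS replicate 1 (0.076), imatinib replicate 2 (0.0568), IMR replicate 1 (0.113) or BMSR replicate 2 (0.0649). Averaged over the 4 arrays of the clones, 19 entries passed, 5 higher and 14 lower. NCAM1 (3.21), RELB (2.60), APOB (2.25), ITGAX (2.03) and GHR (1.81) rose, and TOP2B (-3.41), ALOX5 (-3.24), TCEAL1 (-3.24), TNFSF8 (-3.03), DNMT3B (-2.82), CCNA2 (-2.59) and GADD45A (-2.54) were among those that fell. In BMSR alone, with its replicate 2 turned, TOP2B had 0.16, ALOX5 0.12, DNMT3B 1.65, CCNA2 0.27 and GADD45A 0.74. NCAM1 then had -0.55, RELB -1.12 and ITGAX 0.07. The count was 0 without IMR replicate 1 or BMSR replicate 2, 2 without either combination array, 10 without either imatinib array and 2, both other entries, with the sign of BMSR replicate 2 turned. The G1/S list was lower there as well (1 of 16 called, 3 adjusted over the list alone, adjusted p = 0.041, 0.653 with an estimated correlation). That call ended without IMR replicate 1 (0.395) or BMSR replicate 2 (0.192), with the sign of the latter turned (0.458), with the block (0.0638), without dim spots (0.872), with centring by signal (0.0808) and against no change (0.0732, fry). Averaged over the 6 short-exposure arrays 0 genes passed (limma), 106 had an unadjusted p under 0.05, 43 higher and 63 lower, and the lowest adjusted p was 0.0559, that of HSP90AA1 (-3.04), BAG1 (-2.30), DNAJA1 (-2.18), TOP2B (-2.13) and THRA (1.45) among others. That count was 23 with a block for replicate number (2 higher, 21 lower), 29 with scale normalization, 51 without dim spots and 112 with each spot on its own.

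Of the 18 genes fixed by name beforehand, 8 were on the array and 5 had a value on all arrays. MYC, the growth-promoting transcription factor, lay below mock on 8 of the 9 arrays with a value, with means of -2.77 ± 2.77 after BMS-354825, 1.08 ± 4.22 after imatinib, -2.31 ± 1.31 after the combination, -6.42 ± 0.83 in BMSR and -4.75 on the single IMR array with a value. SOCS2, a STAT5 target, lay below mock on 8 of 10 arrays, with group means from -3.29 to -1.21. BCL6, a repressor that STAT5 holds down, lay above mock on 10 of 10 arrays, with group means from 0.20 to 1.27. The survival gene BCL2L1 had group means from -0.19 to 1.29, and the CDK inhibitor CDKN1B lay below mock on 7 of 8 arrays. These counts take BMSR replicate 2 as deposited: with its sign turned MYC had -0.59 ± 9.08 in BMSR and lay below mock on 7 of 9 arrays, SOCS2 on 7 of 10, CDKN1B on 6 of 8 and TFRC on 9 of 10, BCL6 lay above mock on 9 of 10, and BCL2L1 had -0.78 in BMSR. The immediate-early gene EGR1, a target of ERK signalling, had means of -1.68 after BMS-354825, -1.30 after imatinib, -1.83 after the combination, -0.57 in IMR and -1.02 in BMSR, with SDs from 0.48 to 2.54. Its BMSR mean was 0.59 with the sign of replicate 2 turned. MYC, CDKN1B and ABCB1 lacked values on some arrays and were tested only in the alternative that takes genes with values on both arrays of each group compared, where none passed (limma, lowest adjusted p 0.0539, that of MYC in BMSR). SOCS2 passed in the mean of all 10 arrays (-1.95, adjusted p = 0.0471), and BCL6 and BCL2L1 passed in no comparison.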

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

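Tests chosen after the data were seen are those without dim spots, with centring by signal, with the sign of BMSR replicate 2 turned for lists, named genes and added comparisons, and everything on the 3 added means. The counts of 0 in imatinib and the combination against mock, BMS minus imatinib, combination minus single exposures and clones minus short exposures stayed at 0 (limma) under every alternative run. BMS against mock had 4 calls with each spot on its own. IMR had 1 with each spot on its own, 6 with the replicate block and 1 with centring by signal. BMSR, with 1 call, had 4 with the replicate block (2 up), 4 with genes measured in that group (2 up), 2 with the sign turned (1 up), and 0 with scale normalization, without dim spots, with centring by signal, with the trended robust prior and with only its own arrays. RELB reversed to -1.12 in BMSR and to -0.17 in the mean of the clones with the sign turned, which follows from turning an array at 5.54. The mean of the short exposures, with 0 calls, had 29 with scale normalization, 112 with each spot on its own, 23 with the replicate block and 51 without dim spots. The mean of the clones, with 19, had 4 with scale normalization, 50 with the block, 2 with the sign turned, 4 with the trended robust prior and 0 with only its own arrays. For all 10 arrays, with 65 (13 up, 52 down), there were 175 with each spot on its own (77 up, 98 down), 101 without dim spots (47 up, 54 down), 40 with the trended robust prior (2 up, 38 down), 0 with the sign turned and 47 without centring (4 up, 43 down). The 2 list calls became 0 with an estimated correlation, 0 with fry, 1 with the replicate block, 4 without dim spots, 1 with centring by signal and 1 with the sign turned. The median correlation between profiles, 0.431, was 0.584 without dim spots. Leaving out each array in turn gave 0 to 9 calls for BMSR, 0 to 1 for IMR minus BMSR, 0 to 1 for the mean of the short exposures, 0 to 27 for the mean of the clones, 17 to 60 for all 10 arrays, 0 to 3 list calls and a median correlation of 0.367 to 0.438. A group left with 1 array is assumed to vary like the others. The lower count with only the compared arrays comes with fewer samples, and 229 entries instead of 452 were tested without dim spots; for the other changes the cause was not tested. Correlations over genes called in either group were not run, since too few were called. Dim spots were most frequent on BMS, imatinib and combination replicate 1 and BMSR replicate 2, where 40.2% to 52.7% of the values were dim. The copies of a spot still agreed closely on BMSR replicate 2, with a median SD of 0.38. That SD was 0.78 on BMS replicate 1, 0.87 on imatinib replicate 1 and 0.80 on combination replicate 1.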

Other observations

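Of the tests given here, those of the shared mock, of a dye effect specific to each gene, of the direction of the dye-swapped array, of other RNA on that array and of splits balanced by replicate number were chosen after the result was seen, as were the genes named on that array.

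Lists that passed nowhere in the planned comparisons are given by their lowest adjusted p (limma, camera). Adhesion genes lay higher in BMSR, 9 of 10 above mock with a median of 0.76 (adjusted p = 0.123), and STAT5 targets did in 4 of 6 (0.77, adjusted p = 0.322). With the sign of BMSR replicate 2 turned these were 4 of 10 (median -0.14) and 0 of 6 (-0.85). The STAT5 list includes BCL6, which STAT5 holds down, so its median does not measure STAT5 activity. Targets of p53 had a median of -0.63 after BMS-354825 (adjusted p = 0.178). Anti-apoptotic genes had -0.46 after the combination (adjusted p = 0.406) and G2/M genes -0.17 (adjusted p = 0.593). In IMR minus BMSR, pro-apoptotic genes had -0.38 (adjusted p = 0.535) and signal transduction genes -0.46 (adjusted p = 0.505); with the sign turned the medians were -0.26 and 0.29.

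Lists too small for a test are given by the mean log2 ratio of their members over all 10 arrays, with BMSR replicate 2 as deposited; no gene passed there with its sign turned. The DNA methyltransferase DNMT3B fell (-1.95, adjusted p = 0.0154, below mock on 10 of 10 arrays), and DNMT1 had -0.91 (adjusted p = 0.0582). CDK4, a MYC target and cell cycle kinase, fell (-1.01, adjusted p = 0.0471, 10 of 10 arrays), while NCL had -0.85, HSPD1 -0.45 and TERT -0.01. The sterol regulator SREBF2 fell (-1.14, adjusted p = 0.0476, 9 of 10 arrays). Among FOXO targets GADD45A fell (-2.19, adjusted p = 0.00348, 10 of 10 arrays), and BCL6 had 0.53, CCNG2 0.71 and BCL2L11 0.25. The CDK inhibitors CDKN1A and CDKN3 had 0.92 and -0.92, the ERK targets EGR1 and JUN -1.28 and -0.25, and the erythroid genes TFRC and ANK1 -1.84 and 0.32. The megakaryocyte integrin ITGA2B had -0.49, the myeloid genes ITGAX and CSF1R, the latter also a target of both inhibitors, 0.78 and -0.94, the lymphoid genes IL7R and CD79A 0.51 and -0.01, and the epithelial genes CDH1 and KRT5 0.62 and -0.07. Of the transporters ABCA3 and ABCC1 had 1.02 and -0.06, and of the reference genes GAPDH, which also stands for glycolysis, had 0.89 (adjusted p = 0.0539) and ACTB -0.01. Antioxidant, interferon and unfolded protein response genes had 0 members with a value on all arrays.

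Genes shifted alike across the 10 arrays were the first pattern weighed, 42 of the 65 called entries having the same sign on all 10. A dye bias that follows the recovered spot signal, here the product of the 2 whole numbers, is argued against. Centring within bins of that product left the median correlation between arrays at 0.892 of its value (SD 0.046 over 200 resamples of genes). The recovered signal is a lower bound, so a bias that follows the true signal stays open. Ratios correlated with the recovered signal at Spearman's rho from -0.353 (IMR replicate 1) to 0.0478 (BMS replicate 2). One shared mock RNA that differed from the other cells stays open: the median correlation between profiles was 0.431, below the 0.667 simulated for a mock as variable as the replicates, and the spread of the mock itself was not measured. A dye effect specific to each gene may also take part, because the dye-swapped array correlated with the mean of the other 9 at 0.423 (SD 0.0405), which is what such an effect gives if the ratio is Cy5 over Cy3, and what a common response gives if it is sample over mock. These cannot be told apart without the order of the channels, and a common response to BCR-ABL inhibition and resistance stays open as well.

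Short-exposure arrays followed their replicate number more than their treatment. Dim spots on the replicate 1 arrays are argued against, since the correlation of replicate differences between the 3 groups was 0.567 (SD 0.064) over the 80 genes without dim spots, against 0.361 over all. A trend with the recovered signal that differs between the replicate numbers is argued against too, with 0.356 (SD 0.0357) after centring within bins of the same product. A trend with the true signal stays open. A shared day, culture or batch of mock RNA per replicate number is named nowhere in the labels, and no biological explanation was tested.

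RELB high in the BMSR clone was the third. Dim spots behind it are argued against: none of its 6 spots on the BMSR arrays was dim, with larger numbers from 139 to 1047, so its 4.43 holds no dim value and leaving them out could not change it before the arrays were centred again. In the full test without dim spots it had 4.73 (95% interval 2.27 to 7.19) against 4.43 (2.87 to 5.98), and the call ended because its standard error went from 0.691 to 1.09. On imatinib replicate 1 the RELB spots with a value had 4.48 (larger number 67) and -3.70 (13, dim) as deposited. Without dim spots only the 4.48 stays there, which lies among the values of the BMSR spots (2.63 to 6.14). RELB therefore does not stand apart from that imatinib array in this setting. The direction of the dye-swapped array stays open, since turning its sign gives -1.12, and so does other or mixed RNA on that array, whose correlation with BMSR replicate 1 was 0.249 over the genes tested, against 0.311 with BMS replicate 1 (difference -0.0615, SD 0.0652), while over spots it was 0.3007 against 0.29. A difference of the clone itself stays open, untested.

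On BMSR replicate 2, among named genes with a value on all arrays, the highest values after IL2RA and CCR8 were those of TNFSF4 (6.36, with 0.29 on replicate 1), CCL5 (6.36 and 0.17), CCL17 (5.82 and 1.85), RELB (5.54 and 3.31), NFKB2 (5.44 and 1.63), CCR7 (5.36 and 0.65), CDKN1A (4.70 and 0.43) and CD70 (4.53 and -1.11).

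For the clones against the short exposures, where 0 genes passed (limma), 6 of 100 splits of the 10 arrays into 4 and 6, drawn from 210, gave as many genes at an unadjusted p under 0.05 as the real split, itself included. The real split gave 42 in that fit of 2 groups and the highest other 89, so over these splits chance cannot be excluded. They mix chance with the structure by replicate number, however. The split with 89 set replicate 2 of the 3 short exposures and of BMSR against the rest and called 8 genes past the threshold, and the next, with 82, set replicate 1 of the 3 short exposures and of IMR against the rest. Among the 100 splits with 2 arrays of each replicate number on the side of 4, the real split had the most genes, 42 against 30 for the highest other. With a block for replicate number the comparison of the clones with the short exposures still gave 0 calls (limma), with 47 genes at an unadjusted p under 0.05.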
